A study of Danio rerio with 6 samples.

How the data were processed

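Gene expression was measured on 6 zebrafish Affymetrix arrays, 1 per sample, with 3 arrays of wild-type AB embryos and 3 of embryos carrying a transgene in which a heat shock promoter drives human EWS-FLI1. Per the labels' protocols, RNA came from pools of 40 embryos and 2.5 µg was used to prepare biotin-labelled cRNA. The primer was oligo(dT), so polyadenylated transcripts were read mostly from their 3' ends. The labels call the samples biological replicates, while the clutches and parents behind each pool are not given in the sources used here. The p-values therefore measure the spread between pools.

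The deposited values are log2 RMA values, 1 per probe set and array, rounded to 2 decimals. RMA, the affy package and R 2.2.0 are named per the submitters' processing notes. RMA corrects background, quantile-normalizes between arrays and summarises the probes of a set, so a difference is relative to the whole distribution of an array, and small differences of dim probe sets are compressed. The log base is not stated and was inferred from the range of the values, 1.58 to 13.46. Array medians lay between 5.07 and 5.12. Arrays carry no read depth, and their number, 3 per group, limits the precision. No detection calls were used here. As a reference for background, 44 bacterial and tag control probe sets were taken after the values were seen, and their 95th percentile was 4.23. Of the tested probe sets, 38.8% had a mean at or under it.

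Of 15617 probe sets, 115 manufacturer controls were left out and 15502 were tested. GEO's platform annotation gave 1 gene for 10795 of them and several genes for 135, while 4572 were unlisted and stay unnamed. Symbols were updated through Entrez identifiers against a RefSeq gene table of assembly GRCz12tu, where 10711 of the 10795 matched and 1 symbol changed. That table served only for names and for which genes neighbour each other, and no coordinates are given. In total 8793 genes were measured. cdkn1a and nr0b1, which had been chosen for naming, were not analysed here, and 1 further gene and 1 gene list are not reported here.

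Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 group means, two-sided), and p-values were Benjamini-Hochberg adjusted over the 15502 probe sets. A probe set was called at adjusted p under 0.05. Adjusted p-values of single genes are limma's throughout. Differences are EWS-FLI1 minus control on the log2 scale. Gene lists were tested with camera (preset correlation 0.01) on the probe set with the highest mean per gene, adjusted over 35 lists that held 861 measured genes of 1129 names. Camera with an estimated correlation (statmod 1.5.0) and fry stood beside it. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. RNA integrity was read from 3' minus 5' control probe sets with an exact permutation test, whose smallest possible p is 0.1 for 3 against 3. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

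The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among called probe sets with 1 gene and no overlap between the groups. It also named up to 4 called members per list, or the 2 largest differences where none was called, and a fixed set of genes. Alternatives were a replicate block, leaving out dim probe sets, other scalings, a trended or robust prior, array weights, a stricter threshold, a minimum change (treat), 1 probe set per gene and leaving out each array. The rule's genes were refitted in 12 of these settings, which leave out the trended prior, the stricter threshold, treat and 1 probe set per gene. Of the 125 called probe sets the rule named, 85 were called in each of the 12 that gave a value and 40 lost the call without at least 1 array. Gene lists under 2 other scalings were added after seeing the data.

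The fit was tested on simulated data with the 15502 probe sets and 200 simulated changes. It recovered 65.7% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale, and 18 of 210 calls were false (8.57%). With no change simulated, limma made 0 calls. A list shifted by -0.5 was called, with 0 of the 35 other lists. The simulated probe sets were drawn independently and with the same spread in both groups. The simulation therefore does not show how often lists of correlated genes would be called falsely.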

Results

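Transcripts were measured in zebrafish embryos carrying EWS-FLI1, the human fusion oncogene of Ewing sarcoma, under a heat shock promoter, and in wild-type AB embryos. Expression of the fusion itself was not examined here. Both groups were heat shocked at 39 °C for 30 min at 50% epiboly, when gastrulation begins, and collected after 2 h at 28.5 °C. Each group had 3 arrays, each from 40 pooled embryos. Because the controls received the same heat shock, the comparison addresses which transcripts differ between the lines after the same heat shock. All values are log2 RMA values, and differences are EWS-FLI1 minus control.

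The arrays separated by genotype. The first principal component held 66.5% of the variance, with controls between -27.0 and -18.7 and EWS-FLI1 arrays between 21.4 and 27.4. Correlations across probe sets were 0.991 to 0.994 within controls, 0.998 within EWS-FLI1 arrays and 0.982 to 0.988 between groups. The controls were more variable, with a median SD of 0.135 against 0.0917 (n = 3 each). The 3' minus 5' value of the GAPDH controls was 1.21 ± 0.10 in EWS-FLI1 and 0.83 ± 0.12 in control samples (SD, n = 3 each), a difference of 0.38 (exact permutation p = 0.1). For acta1 the difference was -0.32 (exact permutation p = 0.1), and their mean differed by 0.03 (exact permutation p = 0.9).

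**Figure D1:**
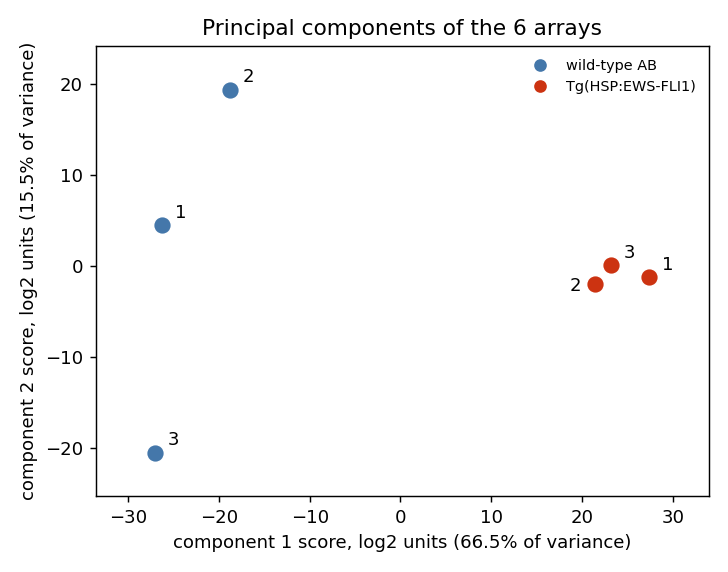
Principal components of the 6 arrays, computed from 15502 probe sets, with the share of variance on each axis. Each point is 1 array. Controls lie between -27.0 and -18.7 on the first component and EWS-FLI1 arrays between 21.4 and 27.4.

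EWS-FLI1 embryos differed from controls at 1835 of 15502 probe sets (11.8%), of which 834 rose and 1001 fell. At 2-fold or more, 211 rose and 135 fell. At 4-fold or more, 61 rose and 9 fell, and at 8-fold or more 22 rose and 3 fell. Called probe sets with 1 gene covered 530 raised and 680 fallen genes, with pcmt and anxa4, named after their values were seen, called in both directions by different probe sets. The groups did not overlap at 29.0% of all probe sets, against 10% by chance. Of the arrays left out in turn, the EWS-FLI1 arrays lowered the counts most: 450 rose and 433 fell without EWS-FLI1 replicate 1, 534 and 572 without replicate 2, and 454 and 519 without replicate 3.

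The largest rise was in unc13d, which encodes a factor of granule exocytosis, from 3.48 ± 0.44 to 9.99 ± 0.30 (SD, n = 3), a difference of 6.51 (SE 0.22, adjusted p = 1.0e-06). The type I collagen gene col1a2 rose by 6.32 (SE 0.13, adjusted p = 6.1e-08), and a second probe set rose by 5.46. tbr1b, a T-box transcription factor of the forebrain, rose by 5.66, the LIM-domain gene fhl3b by 5.31 and the Src-family kinase yrk by 5.11. prkag2a, a regulatory subunit of AMP-activated kinase, rose by 4.59, ppp1r13ba by 4.42, and aanat2, an enzyme of melatonin synthesis, by 4.15. ctxn2 (3.93), the keratin gene krt94 (3.86), the hematopoietic cofactor lmo2 (3.44) and the kinase gene sgk1 (3.03) completed the 12. Of the 61 probe sets raised at least 4-fold, 33 had control means within the background reference, among them 9 of these 12 (all but prkag2a, aanat2 and sgk1), so their fold and rank depend on the background.

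Among fallen genes, ufm1, a ubiquitin-like modifier, fell by 3.43 (SE 0.25, adjusted p = 9.0e-05), from 6.32 ± 0.59 to 2.89 ± 0.12 (SD, n = 3). irg1l changed by -3.07, the nucleophosmin gene npm1b by -3.05 and stmn4 of the stathmin family by -2.45. plekhf1 and the annexin gene anxa2a each changed by -2.16, and lpcat4 by -1.91. tmem263 fell by 2.36, while another of its probe sets fell by 0.36 (adjusted p = 0.0345) and a dim one differed by -0.09. The falls of the following were not shared by the gene's other probe sets: rbfox2 (-2.15, other -0.24), neff1 (-1.98, other 0.30) and copb2 (-1.87, others 0.29 and 0.06). The call of copb2 (adjusted p = 0.0495) was lost when control replicate 1 or 3 or any 1 EWS-FLI1 replicate was left out (highest adjusted p = 0.167), and that of irf1b (-1.92, adjusted p = 0.0199) without EWS-FLI1 replicate 1 or 3 (highest adjusted p = 0.0934). Of the 9 probe sets that fell at least 4-fold, 3 (ufm1, irg1l and stmn4) had EWS-FLI1 means within the background reference, as had neff1, irf1b and copb2, so the size of these falls depends on the background.

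**Figure D2:**
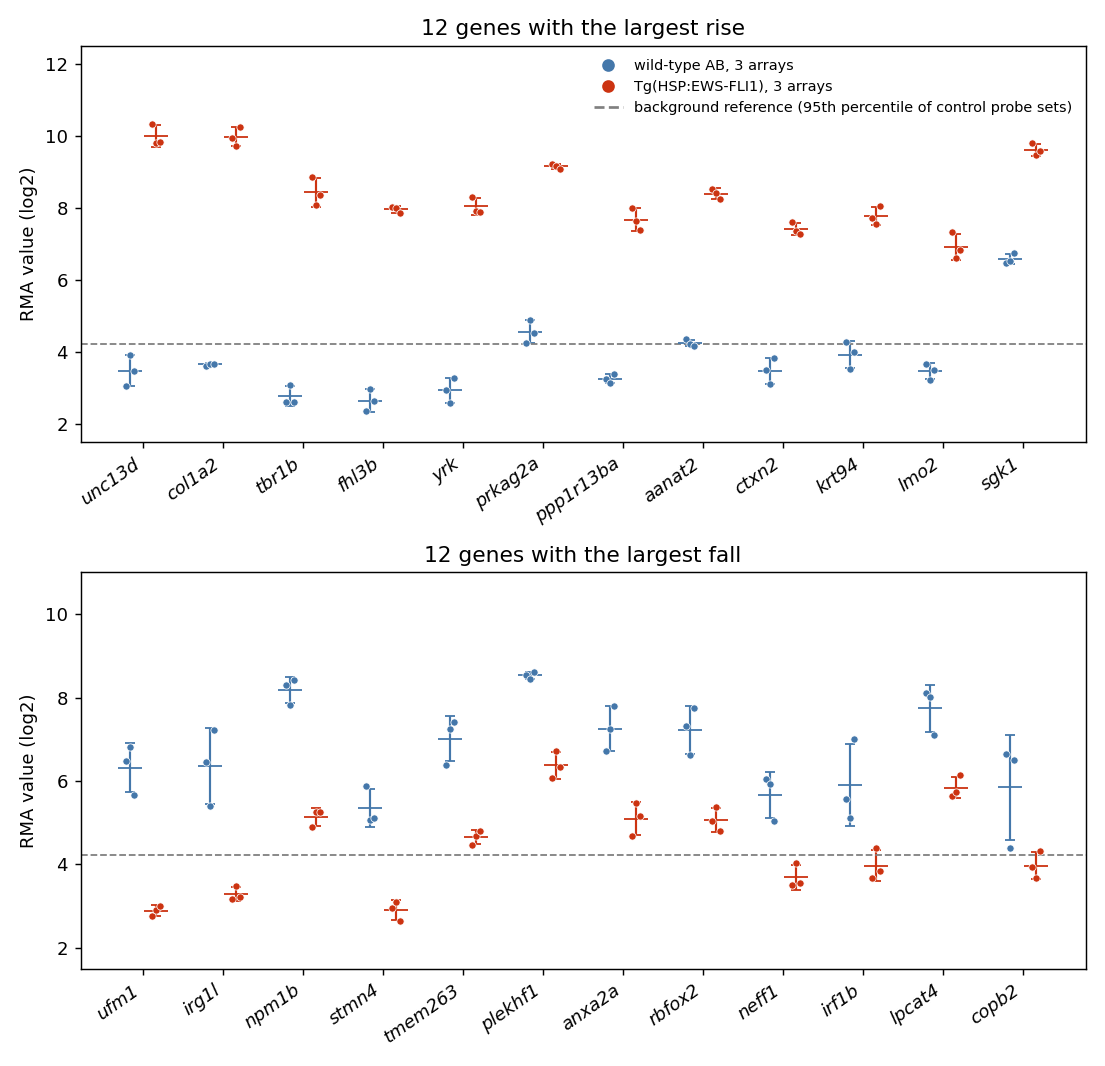
Log2 RMA values of the 12 genes with the largest rise and the 12 with the largest fall, 1 point per array (3 control, 3 EWS-FLI1), with bars for the mean ± SD of each group and a dashed line at the background reference, 4.23. unc13d differs by 6.51 and ufm1 by -3.43.

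Genes of the neural plate, the precursor of the brain and spinal cord, fell as a group. Of 45 measured, 27 fell, 4 rose and 14 were not called (32 fell and 4 rose adjusted over the list alone), with a median of -0.73 (camera adjusted p = 4.2e-12). The eye-field gene rx3 fell by 1.33 (SE 0.16), the progenitor factor sox2 by 0.87 (SE 0.09) and the Hairy-related repressor her3 by 1.16 (SE 0.13). pax6a (-1.74, EWS-FLI1 mean within the background reference) lost its call when any 1 EWS-FLI1 replicate was left out (highest adjusted p = 0.0724). The 4 that rose were irx3a (1.28), irx1a (0.98), neurog1 (0.97) and sox11a (0.67), the last 3 named after their values were seen. Of 24 neural crest genes, 8 fell and 16 were not called (12 fell adjusted over the list alone), among them foxd3 (-1.42) and twist1a (-0.91), with a median of -0.35 (camera adjusted p = 1.6e-05). Of 31 ventral ectoderm and BMP response genes, 11 fell, 1 rose and 19 were not called (18 and 3 adjusted over the list alone; median -0.42, camera adjusted p = 2.1e-06). They included the epidermal factor tp63 (-1.33), dlx3b (-0.97) and tfap2a (-0.88), while bmper, named after its value was seen, rose by 0.36. For each of these 3 lists the adjusted p was 0.231 with an estimated correlation.

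Mesodermal and axial genes also moved downward, with exceptions. In the mesoderm and tailbud list, 13 of 27 fell, 2 rose and 12 were not called (18 fell and 2 rose adjusted over the list alone; median -0.43, camera adjusted p = 4.0e-06). tbx16l fell by 0.97, fgf8a by 0.96 and tbx6 by 0.84, while tbxta, the zebrafish Brachyury gene, rose by 0.54 (SE 0.11) and tbx1, named after its value was seen, by 0.70. tbx16 differed by -0.41 (adjusted p = 0.124), and its second, dimmer probe set fell by 1.22 (adjusted p = 2.6e-04). In the organizer and axial mesoderm list, 15 of 24 fell, 2 rose and 7 were not called (17 and 3 adjusted over the list alone; median -0.63, camera adjusted p = 2.1e-06). The organizer genes gsc and chrd each changed by -0.91 (SE 0.12 and 0.09), whereas foxa rose by 2.88 (SE 0.09) and the BMP antagonist nog2 by 1.12 (control mean within the background reference). Of 14 endoderm genes, 3 fell (foxa1 -1.11, cxcr4b -0.94, cxcr4a -0.84), the pancreatic factor pdx1 rose by 2.55 (control mean within the background reference) and 10 were not called (6 fell and 1 rose adjusted over the list alone; median -0.23, camera adjusted p = 0.0176). sox17 differed by -0.03 (adjusted p = 0.938). The endoderm call was lost without control replicate 1 or 2 (highest adjusted p = 0.0667), and for each of the 3 lists the adjusted p was 0.231 with an estimated correlation.

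Hox and cdx genes, which pattern the head-to-tail axis, fell at 20 of 48 members, with 28 not called (24 fell and 1 rose adjusted over the list alone; median -0.50, camera adjusted p = 9.5e-11). hoxb1a fell by 1.40 (SE 0.22), and hoxb3a (-1.07) lost its call without EWS-FLI1 replicate 1 (adjusted p = 0.0505). The hox list had an adjusted p of 0.307 with an estimated correlation. In the Notch and her list, 17 of 30 fell, 1 rose and 12 were not called (19 and 2 adjusted over the list alone; median -0.55, camera adjusted p = 1.8e-07). her2 fell by 0.96 and her6 by 0.93, and the ligand gene jag1a, named after its value was seen, rose by 0.72. The adjusted p for Notch was 0.231 with an estimated correlation.

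In Wnt signalling, 13 of 30 genes fell and 17 were not called (17 fell adjusted over the list alone; median -0.34, camera adjusted p = 9.7e-07). The largest falls were in the secreted antagonist sfrp1a (-1.64, SE 0.18), the receptor fzd8b (-1.50, SE 0.18), the T-box factor tbx16l (-0.97, SE 0.17) and the antagonist dkk1b (-0.95, SE 0.10). In the FGF and ERK response list, 10 of 23 fell, 1 rose and 12 were not called (11 and 1 adjusted over the list alone; median -0.51, camera adjusted p = 2.7e-05). The ligand genes fgf24 (-1.14) and fgf8a (-0.96) and the ETS factor etv4 (-0.90) fell, and the phosphatase gene dusp5 rose by 1.50 (control mean within the background reference). In the Hedgehog list, 6 of 16 fell, including hhip (-0.90) and shhb (-0.80), and 10 were not called (7 fell adjusted over the list alone; median -0.23, camera adjusted p = 4.5e-05). In the Nodal list, 6 of 21 fell, including lft1 (-0.89) and noto (-0.87), and 15 were not called (8 fell adjusted over the list alone; median -0.29, camera adjusted p = 5.8e-04). Their adjusted p with an estimated correlation was 0.259 for FGF and 0.231 for each of the others.

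Genes of cell movement in gastrulation fell at 15 of 41 members and rose at 3, with 23 not called (22 and 3 adjusted over the list alone; median -0.33, camera adjusted p = 5.0e-06, adjusted p = 0.231 with an estimated correlation). stat3 fell by 1.28 (SE 0.09) and the hyaluronan synthase gene has2 by 0.97 (EWS-FLI1 mean within the background reference), while the planar polarity gene prickle1b rose by 1.38, the integrin gene itga5 by 1.34 and gna12a, named after its value was seen, by 0.61. In the early gastrula list, 11 of 26 fell and 15 were not called (12 fell adjusted over the list alone; median -0.31, camera adjusted p = 4.0e-06, adjusted p = 0.231 with an estimated correlation). In the late gastrula and somite list, 17 of 35 fell, 3 rose (lmo2, egr2b and neurog1) and 15 were not called (20 and 3 adjusted over the list alone; median -0.53, camera adjusted p = 4.3e-06, adjusted p = 0.328 with an estimated correlation).

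In the enveloping layer, the outer covering of the embryo, the keratin genes krt94 (3.86) and krt18b (2.51) rose from control means within the background reference, 6 of 27 genes fell and 19 were not called (9 fell and 2 rose adjusted over the list alone). The list's median was -0.17 and its mean 0.03. Camera placed it downward (adjusted p = 0.0337, 0.465 with an estimated correlation), and fry did not call it (adjusted p = 0.328). The camera call was lost with the replicate block and without control replicate 1 or 2 or EWS-FLI1 replicate 1 or 2 (highest adjusted p = 0.13). Of 21 genes of the yolk syncytial layer, a nutritive layer under the embryo, 4 fell, among them the fibronectin genes fn1b (-0.80) and fn1a (-0.59), and 17 were not called (6 fell and 2 rose adjusted over the list alone; median -0.20). Its camera adjusted p was 0.0176 (0.354 with an estimated correlation) and 0.0731 without control replicate 2, and its fry adjusted p 0.0583. Other probe sets of fn1a were not called (-0.30 and -0.14, adjusted p = 0.23 and 0.58).

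**Figure D3:**
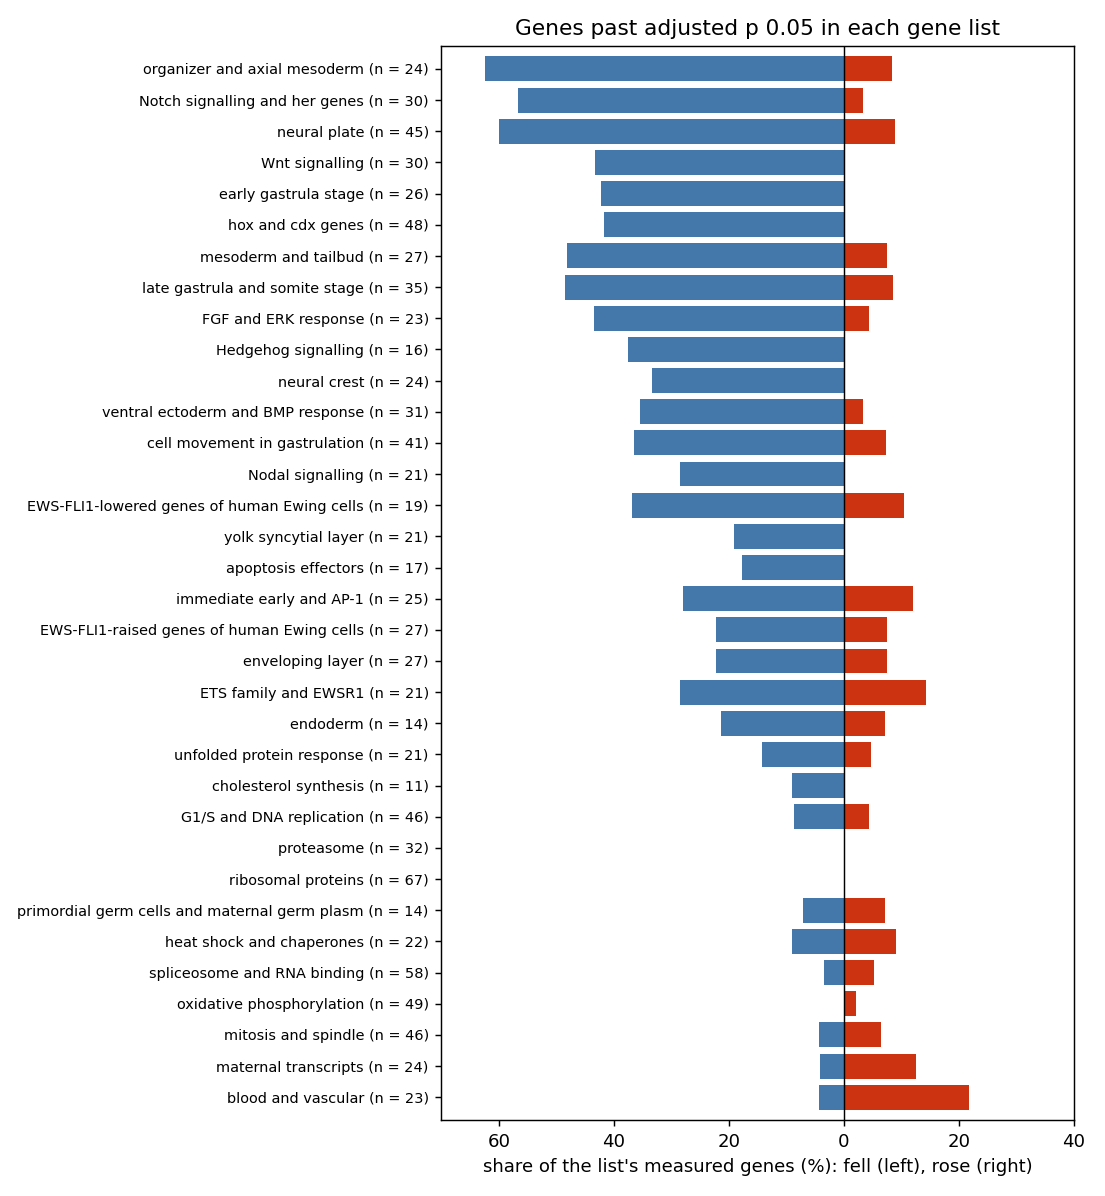
Share of each list's measured genes (n beside the name, in %) that fell (blue, left) or rose (red, right) at adjusted p under 0.05, for the lists reported. In the neural plate list 27 of 45 fell and 4 rose, and in the blood and vascular list 5 of 23 rose and 1 fell.

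Of 17 apoptosis effectors, 3 fell, the inhibitor birc2 (-1.01) most, followed by bcl2l1 (-0.38) and bida (-0.29), and 14 were not called (7 fell and 1 rose adjusted over the list alone; median -0.14, camera adjusted p = 0.0955, fry downward with adjusted p = 0.0164). bcl2l1 lost its call when any 1 EWS-FLI1 replicate was left out (highest adjusted p = 0.0922) and bida when any 1 of the 6 arrays was left out (highest adjusted p = 0.145). Another probe set of bcl2l1 was not called (-0.23, adjusted p = 0.17).

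The chaperone list, which includes the heat shock genes, showed no common direction: hsp90aa1.1 rose by 2.93 and hspb8 by 2.44, serpinh1b changed by -1.0 and dnajb1b by -0.38, and 18 of 22 were not called (3 fell and 2 rose adjusted over the list alone; median -0.01, mean 0.16, camera adjusted p = 0.995). hsp70.3, whose probe set was among the dim ones left out in an alternative setting, differed by 0.22 (adjusted p = 0.345). dnajb1b lost its call when control replicate 1 or any 1 EWS-FLI1 replicate was left out (highest adjusted p = 0.147). In the unfolded protein response, hsp90b1 rose by 0.95, dnajc3a (-0.87), atf4a (-0.69) and atf3 (-0.74) fell, and 17 of 21 were not called (6 fell and 2 rose adjusted over the list alone; median -0.14, camera adjusted p = 0.067). atf3 lost its call when any 1 EWS-FLI1 replicate was left out (highest adjusted p = 0.0625). Of 25 immediate early genes, 7 fell, 3 rose and 15 were not called (11 and 4 adjusted over the list alone; median -0.22, camera adjusted p = 0.0574). The 3 that rose were egr2b (2.37), dusp5 (1.50) and klf6a (0.37, named after its value was seen), and egr2b lost its call without EWS-FLI1 replicate 1 (adjusted p = 0.0534).

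Genes of blood and vessels rose at 5 of 23 members: lmo2 (3.44), the endothelial receptor genes tie1 (1.37), kdrl (0.90) and tek (0.56), and the ETS gene fli1rs (1.11). vegfaa changed by -0.58 and 17 were not called (7 rose and 3 fell adjusted over the list alone; tek and vegfaa were named after their values were seen). All 5 that rose had control means within the background reference, as vegfaa had in both groups, so the size of these differences depends on the background. The list's median was -0.01 and its mean 0.30 (camera adjusted p = 0.117, fry adjusted p = 0.0324), and the red-cell genes hbae3 (-0.29) and gata1a (-0.14, within the background reference in both groups) were not called. Among 21 ETS family genes and EWSR1, etv6 (1.30), fli1rs (1.11) and gabpa (0.73, named after its value was seen) rose, 6 fell, including etv4 (-0.90) and etv5a (-0.85), and 12 were not called (5 rose and 7 fell adjusted over the list alone; median -0.03, camera adjusted p = 0.56). The zebrafish counterparts of the fusion partners include fli1rs, also listed as fli1b, which rose by 1.11 (adjusted p = 6.5e-04). For fli1 the difference was 0.29 (adjusted p = 0.0789), and its second probe set rose by 1.25. The differences were 0.09 for ewsr1a (adjusted p = 0.558) and 0.15 for ewsr1b (adjusted p = 0.287), and erg gave -0.10 (adjusted p = 0.669). erg and both fli1 probe sets lay within the background reference in both groups.

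Genes that EWS-FLI1 raises in human Ewing cells had 2 raised, 6 fallen and 19 uncalled members of 27 (2 and 6 adjusted over the list alone; median -0.07, camera adjusted p = 0.136, fry downward with adjusted p = 0.0317). egr2b (2.37) and jag1a (0.72, named after its value was seen) rose, while nkx2.2b (-0.91, EWS-FLI1 mean within the background reference), sox2 (-0.87) and the caveolin gene cav1 (-0.84) fell. nkx2.2a (-0.24, adjusted p = 0.284), gli1 (-0.07, adjusted p = 0.709) and myca (-0.28, adjusted p = 0.208) lay within the background reference in both groups, so their values do not show whether they changed. ccnd1 (-0.54) lost its call without EWS-FLI1 replicate 1 or 3 (highest adjusted p = 0.0732). Genes that it lowers in human Ewing cells had 7 fallen, 2 raised and 10 uncalled members of 19 (7 and 3 adjusted over the list alone; median -0.16, mean 0.06, camera adjusted p = 0.128). dkk1b (-0.95) fell, and col1a2 (6.32) and tgfbr2b (0.50, named after its value was seen) rose.

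Of 46 DNA replication genes, 4 fell (gins2 -0.80, ccnd1 -0.54, mcm2 -0.46, prim1 -0.44), 2 rose (orc4 0.54, cdk1 0.40) and 40 were not called (4 and 2 adjusted over the list alone; median -0.02, camera adjusted p = 0.334). Of 46 mitosis genes, 3 rose (kif18a 0.55, prc1a 0.53, ect2 0.43), 2 fell (cdca8 -0.59, numa1 -0.48) and 41 were not called (4 and 3 adjusted over the list alone; median 0.02, camera adjusted p = 0.86). Of 58 spliceosome genes, snrpa (-0.81) and srsf5b (-0.47) fell, sf3b5 (0.58), prpf31 (0.41) and snrpb (0.38) rose, and 53 were not called (3 rose and 2 fell adjusted over the list alone; median 0.07, camera adjusted p = 0.128). prim1, cdk1, ect2 and snrpb were named after their values were seen. Calls were lost for gins2 without control replicate 1 or any 1 EWS-FLI1 replicate (highest adjusted p = 0.135), mcm2 without EWS-FLI1 replicate 1 or 3 (highest 0.0658), kif18a without EWS-FLI1 replicate 1 (adjusted p = 0.0592), srsf5b without EWS-FLI1 replicate 1 or 2 (highest 0.0598) and prc1a without EWS-FLI1 replicate 3 (0.0513). Those of numa1 (highest adjusted p = 0.101), cdca8 (0.137), sf3b5 (0.104) and prpf31 (0.135) were lost when control replicate 1 or any 1 EWS-FLI1 replicate was left out, and the last 3 also without control replicate 3.

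In the proteasome list, limma called 0 of 32 genes, with 4 raised at unadjusted p under 0.05 and 0 called adjusted over the list alone. Its median was 0.08, with psmd3 at 0.25 (adjusted p = 0.159) and psmc1b at 0.23 (adjusted p = 0.204). Camera placed the list upward (adjusted p = 0.019, 0.465 with an estimated correlation), and fry did not (adjusted p = 0.111). The camera call was lost without control replicate 1 or 2 (highest adjusted p = 0.0851). Of 67 ribosomal protein genes, limma called 0, with 0 at unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.01, camera adjusted p = 0.51, fry adjusted p = 0.718). rps27.1 differed by -0.16 and rps26 by 0.11. Of 49 oxidative phosphorylation genes, atp5mc1 rose by 0.44 and 48 were not called (median 0.09, camera adjusted p = 0.0574), with 6 raised at unadjusted p under 0.05 and 0 called adjusted over the list alone. Of 11 cholesterol synthesis genes, acat2 fell by 0.39 and 10 were not called (1 fell adjusted over the list alone; median -0.01, camera adjusted p = 0.86). atp5mc1 and acat2 lost their calls when control replicate 1 or 3 or any 1 EWS-FLI1 replicate was left out (highest adjusted p = 0.116 and 0.125).

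Of 8793 genes, each read by its brightest probe set, 497 rose and 626 fell, and markers of germ cells and of maternal transcripts were called in both directions. Of 14 germ cell genes, tdrd6a rose by 0.57 (within the background reference in both groups), cxcr4b changed by -0.94 and 12 were not called (1 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.255). Of 24 maternal transcripts, 3 rose (org 0.97, zp3a.1 0.62, zar1 0.43), sox19b changed by -0.68 and 20 were not called (3 and 1 adjusted over the list alone; median -0.08, mean 0.01, camera adjusted p = 0.865). When any 1 EWS-FLI1 replicate was left out, the calls of sox19b (highest adjusted p = 0.129), org (0.129), zp3a.1 (0.169) and zar1 (0.172) were lost, those of org, zp3a.1 and zar1 also without control replicate 1, and those of zp3a.1 and zar1 without control replicate 3.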

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

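Both tests of the control probe set described here were chosen only after its values were seen, and 1 of them was then limited to probe sets above background, with the same verdict before and after.

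Among the 115 control probe sets left out of the comparison, the groups did not overlap for 7, and 1 of these, AFFX-Dr-U43284-1_s_at, was more than 2-fold higher in EWS-FLI1 samples. It read 7.01, 4.86 and 6.62 on the controls and 9.94, 9.74 and 9.47 on the EWS-FLI1 arrays, a difference of 3.55 (exact permutation p = 0.1, the smallest possible). Carry-over of EWS-FLI1 RNA into control replicates 1 and 3 would need shares of 12.3% and 8.53%, and the genes raised at least 4-fold then lay below the required level by more than it allows (median observed minus required -0.95 and -0.65). That argues against carry-over as the cause of the higher values on control replicates 1 and 3, 7.01 and 6.62 against 4.86 on replicate 2. Sequence carried by the transgene may account for the difference of 3.55, but the construct's sequence was not used here, so it stays open.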

How the results depend on the processing

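The gene lists under median centring and repeated quantile normalization were chosen only after the data were seen. The 139 probe sets named by the rule were refitted in 12 settings, and genes named after their values were seen were not. These settings do not include the stricter threshold, treat, the trended prior or 1 probe set per gene. Of the 139, all 125 called ones kept their sign in each setting that gave a value (101 had one without dim probe sets), and 85 stayed called in all of these. Without a block for the replicate number 834 probe sets rose and 1001 fell; with the replicate block 705 rose and 871 fell, 352 changed 2-fold and 17 lists passed, 1491 of the 1576 calls being shared. Same-numbered arrays did not deviate together (correlations of deviations -0.082, -0.099 and -0.076), so the numbers only name samples. Raised counts were 504 with 1 probe set per gene (fewer tests), 415 at adjusted p under 0.01 and 162 with treat (a minimum change of 0.5). Fallen counts were 628, 411 and 57 in the same settings. Leaving out 1 array gave 450 to 1023 raised, 433 to 1286 fallen, 278 to 453 at 2-fold and 14 to 20 lists. 2-fold changes numbered 228 without dim probe sets and 215 with 1 probe set per gene. Median centring and quantile normalization gave 852 and 865 raised and 1000 and 973 fallen, and among lists only cholesterol synthesis changed the sign of its median. With an estimated correlation, camera called 0 lists (5 at unadjusted p under 0.05), and fry called 17 downward and 2 upward. For the lists called with the preset of 0.01, the estimated correlations lay between 0.020 and 0.40, other than -0.0019 for endoderm. The unadjusted camera p of endoderm still rose from 0.0075 to 0.0468, so a higher correlation is not the only reason for the lost calls. The first principal component held 82.8% over the 1000 most variable probe sets and 72.2% without dim ones, where the cause was not tested. The integrity difference was 0.38 for GAPDH and -0.32 for acta1, opposite in sign, where the cause was not tested. Dim signal limits folds, since 267 raised probe sets had control means within the background reference.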

Other observations

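The tests chosen only after the results were seen were the stage and chaperone tests, the test on other probe sets of a gene, and the neighbour test at 2-fold. The single genes named in the next paragraph were also chosen after their values were seen.

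Single genes outside the fixed lists that rose in EWS-FLI1 embryos included pxna of focal adhesions (2.96), the membrane metalloprotease mmp14b (2.35), the collagen gene col9a2 (2.39), and the receptors plxnd1 (2.26) and robo1 (2.14). The serotonin synthesis genes tph2 (1.98) and tph1b (1.72) rose, as did the iron exporter slc40a1 (2.69). Lower transcripts included the tight junction gene cldn3d (-1.87), lgals3b (-1.68), the nuclear receptor nr2f5 (-1.39) and the growth factor gene bmp3 (-1.55). These are single genes, and no theme was tested. By name stem, col genes had 4 raised and 2 fallen members of 21 (adjusted p = 0.53).

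By Fisher's exact test, 4 of 131 name stems held more called genes than the share over all 7809 genes with a stem, 12.9%. The test takes the genes of a family as independent. Estimated correlations were 0.40 in the hox and cdx list and 0.20 in the Notch and her list, so its p-values may be too small. For her genes 10 of 11 fell (adjusted p = 1.6e-06), for hoxb genes 10 of 13 fell (adjusted p = 1.6e-05), for fzd receptors 5 of 8 fell and fzd2 rose (adjusted p = 0.0044), and for sox genes 7 of 18 fell and sox11a rose (adjusted p = 0.0322). Most of these genes were in the fixed lists (9, 13, 5 and 13), so the families restate part of those falls. Among the fallen, her1 and her4.2 lay within the background reference in both groups, so their values do not show whether they changed. hoxb5a and hoxb6b had EWS-FLI1 means within it, so the size of their falls depends on the background. Adjacent measured genes with different stems were called in the same direction in 99 pairs, against a median of 69 in 10000 shuffles (permutation p = 1e-04, the smallest possible). Only 35 of the pairs had no other coding gene starting between them, and 4 overlap. Raised pairs numbered 48 (shuffled median 26, permutation p = 1e-04) and fallen pairs 51 (shuffled median 43, permutation p = 0.103), a contrast that was not itself tested. At 2-fold, 7 pairs rose together (shuffled median 2, permutation p = 0.0029), among them cox4i1l with prkag2a, and, with 1 coding gene starting between, zdhhc24 with foxa and pcsk1nl with hdac6. The cause was not tested.

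The fall of 17 lists, which share members, was set against 4 explanations. An intensity-dependent shift is argued against because genes of the same brightness did not fall. For the 17 lists, the medians of random lists matched on brightness lay between -0.013 and 0.013. All 17 of the 17 list medians lay under the 2.5th percentile of these random lists. That count adds little, since the lists were chosen for falling and the random draws do not keep the correlation between genes. An earlier stage would leave the early gastrula list at 0 or above, and it fell too (median -0.31), while a later stage would raise the late list, which fell (median -0.53). Fry called both falls (adjusted p = 0.02 and 0.0434), and with an estimated correlation both calls were lost (adjusted p = 0.231 and 0.328). Genes of both stages thus fell. Both lists are among the 17 to be explained, and the early list shares 11 members with the Nodal list. The tests therefore cannot decide on a stage difference, which stays open. A stronger heat shock response stays open, since the chaperone median of -0.0083 covers members that went both ways. An effect of EWS-FLI1 on embryonic patterning is a hypothesis that was not tested, and other differences between the lines, such as clutch or parents, were not tested either. Siblings with and without the transgene, heat shocked alike, would separate these.

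For changes of at least 2-fold, a sequence difference between the lines under single probe sets was tested on genes with another probe set above background, and the test was changed after its first result. By the first reading, the other probe set moved the same way in 8 of 11 raised genes (72.7%, exact interval 39.0 to 94.0) and 16 of 21 fallen genes (76.2%, 52.8 to 91.8); by the second, it was called the same way in 54.5% and 61.9%, against 5.38% and 6.46% of all probe sets, a share not matched on brightness. For the fallen genes as a set the first interval lay above 50 and the called share above that of all probe sets. Several agreeing pairs, such as those of tp63 and pax2a, carry the same cluster number, however, and may share target sequence. A sequence difference could move both probe sets of such a pair, so their agreement cannot exclude it. For the 5 largest falls tested, rbfox2, neff1 and copb2 among them, the other probe set was not called. Only 2 of the 21 other probe sets fell 2-fold, so for the fallen genes a sequence difference stays open. The raised genes, only 11 of which could be tested, also stay open because the first interval holds 50. A haplotype linked to the transgene that caused most of the changes would put most such genes on 1 chromosome. The largest shares were 8.21% of raised and 9.28% of fallen genes, against 5.72% and 4.58% of all measured genes on those chromosomes. The test cannot exclude a linked haplotype behind some of the genes. A sequence difference may therefore still lie behind single genes.

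The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For the raised, fallen and 2-fold counts and for the lists, 1 split of 10, the real one, gave as large a value. The real counts were 834, 1001 and 346, against 0 for the highest other split by limma (260 to 671 at unadjusted p under 0.05), and 18 lists against 17. Each other split still keeps part of the group difference. Each also mixes the lines on both sides, which puts much of that difference into the spread within a side and leaves limma few calls. The counts of 0 therefore say little about chance.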
